A study of Mus musculus with 3 samples.

How the data were processed

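The samples were 3 chromatin immunoprecipitation libraries from bone marrow hematopoietic stem cells of mice aged 24 months: 1 for H3K27ac, 1 for H3K4me1 and 1 of input DNA. Groups were taken from the sample titles. Peak lists of the 2 marks were used, and the input library was not analysed here. Per the labels' protocols, nuclei were sonicated, DNA bound to the marked histones was isolated with an antibody and libraries were made with a ThruPLEX kit. Bowtie2 2.0.6, MACS2 2.0.10.20131216 and the mouse build mm9 are named in the submitters' processing notes. Mapping filters, duplicate handling, the options of the peak caller and its control were not given in the sources used here. The last peak passes the mm10 chromosome end on 8 of 21 chromosomes and the mm9 end on 0, so coordinates are those of mm9 and are printed counting from 1.

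Each deposited list was called on 1 library and holds, per peak, its position, the summit offset and 4 values from the peak caller. The authors' fold is the ratio of the summit pileup to the local background. The deposited −log10 p and −log10 q values belong to the summit, and the lowest −log10 q is 1.30 in H3K27ac and 1.31 in H3K4me1, close to a q of 0.05. The deposited score is the −log10 q times 10 cut to a whole number, and was not used. No peaks overlapped within a list, so each peak was 1 region.

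Depth was read from the lists. Fold values stepped by 0.295 in H3K27ac and 0.211 in H3K4me1, and 71.5% and 60.3% of them were whole multiples of the step within 0.01 of a step. Fold and −log10 p together fix the number of reads at the summit and the local background, if fold is (reads + 1)/(background + 1) and p is the Poisson probability of more reads than observed. A whole number of reads gave the deposited −log10 p within 0.001 for all 93413 H3K27ac and all 155027 H3K4me1 summits. The recovery was tested on simulated data with known reads, where it returned 99.997% of 93413 H3K27ac and 99.998% of 155027 H3K4me1 summits. The simulated values were made with the same formulas, so this checks the calculation and not whether the peak caller used them. The genome-wide background was 2.38 reads for H3K27ac and 3.75 for H3K4me1. Taking the shortest peaks, 185 and 196 bp, as the fragment length, which is an assumption, gives 12.9 and 19.1 fragments per kb. The weakest summits held 8 and 10 reads. A local background more than 1.05 times the genome-wide one was called raised and was found at 26.2% of H3K27ac and 36.8% of H3K4me1 summits. Where summits of the 2 marks lay within 20 bp, 668 of the 697 H3K27ac summits with a raised background were raised in H3K4me1 as well, and over these 668 summits, which are not independent replicates, the log2 ratios to the genome-wide level correlated with a Pearson r of 0.964 and a Spearman rho of 0.837.

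Regions were compared by sharing at least 1 bp. Shares have exact Clopper-Pearson 95% intervals. Chance overlap was described by 100 placements of each region at a random position of its own mm9 chromosome, with lengths from GenomeInfoDb 1.38.1 and without leaving out assembly gaps. In a further description, chosen after seeing the data, all regions of a chromosome were moved by the same random distance, which gave 10.2% for H3K27ac and 5.56% for H3K4me1. H3K27ac regions were joined over gaps of up to 12.5 kb into domains, ranked by acetylated length. Before the data were examined, the named items were set as the 10 first domains and the 5 regions of highest fold in each class. The classes of fold and width, the positions around summits, the summit reads and the counts per chromosome were chosen after seeing the data. Interval functions and random placement were tested on simulated regions, where random lists overlapped 0.998 times as often as chance. The lists and the chance level came from the same placement step. The value therefore checks the calculation and not whether random placement suits these data.

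The alternatives changed the overlap rule, the q threshold, the number of regions, the joining of regions, the domain gap and ranking. Planned comparisons with gene start sites and gene lists were not made, because the gene table at hand is on assembly GRCm38 and no mm9 annotation was used here. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.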

Results

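Histone modifications were profiled by chromatin immunoprecipitation sequencing in hematopoietic stem cells from the bone marrow of C57BL/6 mice aged 24 months. The cells were isolated as SP-KSL-CD150+ cells. KSL is the usual gate for primitive bone marrow cells that carry c-Kit and Sca-1 and lack lineage markers, and CD150 is a surface antigen of stem cells. H3K27ac, an acetylation found at active promoters and enhancers, and H3K4me1, a methylation found at enhancers and beside active promoters, were each measured in 1 library, and an input library accompanied them. Each library is described as a technical replicate of biological replicate 1, so no difference below has a replicate check and no p-value is given. The marks were mapped within a study of long non-coding RNAs in stem cells, and the comparison open to these data is which acetylated regions also carried H3K4me1. The input library was not analysed here. At the background level the H3K27ac library held 12.9 fragments per kb and the H3K4me1 library 19.1, a ratio of 1.48 that rests on an assumed fragment length and stands here for the difference in depth. A peak summit held a median of 13 reads for H3K27ac (quartiles 11 and 18) and 20 reads for H3K4me1 (quartiles 16 and 28). Intervals of shares are exact 95% binomial intervals over the regions of these libraries. They cover counting error only, since reads without molecular identifiers are not independent molecules and neighbouring regions are not independent samples.

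H3K4me1 occupied more and wider stretches of the genome than H3K27ac. There were 155027 H3K4me1 regions covering 173.6 Mb, or 6.54% of the mm9 chromosomes, and 93413 H3K27ac regions covering 55.9 Mb, or 2.11%. The median H3K4me1 region was 687 bp wide (quartiles 360 and 1360 bp) and the median H3K27ac region 355 bp (quartiles 243 and 668 bp). H3K4me1 formed 458 regions of 10 kb or more, against 9 for H3K27ac. H3K27ac reached higher enrichment, with a highest summit of 43.4-fold over background against 15.4-fold for H3K4me1, although the median summits were 3.86-fold and 4.12-fold. These fold values are the authors' own, from their peak caller. The 1.66-fold difference in region number is not separated from a difference in depth between the libraries.

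Most acetylated regions carried H3K4me1, whereas most H3K4me1 regions lacked H3K27ac. Of the H3K27ac regions, 67009 (71.7%, interval 71.4 to 72.0%) shared at least 1 bp with an H3K4me1 region, and 26404 did not. Of the H3K4me1 regions, 52085 (33.6%, interval 33.4 to 33.8%) shared at least 1 bp with an H3K27ac region, and 102942 carried H3K4me1 alone. The 2 marks shared 36.8 Mb, which was 65.9% of the acetylated length and 21.2% of the H3K4me1 length. When the H3K4me1 regions were placed at random on their own chromosomes, 10.1% of H3K27ac regions met one on average (range 9.89 to 10.5% over 100 placements), so the observed share was 7.08 times as high. In the other direction random placement gave 6.16%, and the observed share was 5.45 times as high. Both ratios mix regional density with local overlap, because random placement does not keep the parts of the genome where both marks cluster. The numbers of regions in autosomal windows of 1 Mb correlated between the marks with a Spearman rho of 0.964. The first share was 50.2% when regions with a raised local background were left out of both lists, a setting chosen after the data had been seen that also removes partners. The second share rose from 33.6% to 47.6% when only the 93413 strongest H3K4me1 regions were kept.

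Regions with both marks were stronger and wider than regions with 1 mark. The median H3K27ac summit was 4.37-fold (quartiles 3.55 and 5.91) where H3K4me1 was present and 3.50-fold (quartiles 2.95 and 3.84) where it was not, and the median widths were 448 and 252 bp. H3K4me1 regions with H3K27ac had a median summit of 5.69-fold (quartiles 4.37 and 7.16) and a median width of 1396 bp, against 3.58-fold (quartiles 2.95 and 4.63) and 493 bp for H3K4me1 alone. The quartile ranges overlapped for H3K27ac and for H3K4me1. When both lists were cut to a −log10 q of at least 10, the ratio of the 2 H3K27ac medians was 1.03, against 1.25 over all regions. H3K27ac peaks that met only weaker H3K4me1 regions then counted as without H3K4me1. Wider regions also meet another mark more easily by position alone. Within the narrowest, middle and widest tertiles of H3K27ac width the ratio was 1.09, 1.08 and 1.13. No such split by width was made for the fold of H3K4me1 regions.

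The share of H3K4me1 regions with H3K27ac rose with the strength and width of the H3K4me1 region. It was 9.84% below 3-fold (29719 regions), 37.7% from 4-fold to 6-fold (52013 regions) and 92.3% at 10-fold or more (1736 regions, interval 91.0 to 93.5%). Of the 58651 H3K4me1 regions under 500 bp, 11.2% had H3K27ac. Of the 2700 regions from 5 to 10 kb, 95.5% had it, and of the 458 regions of 10 kb or more 99.6% did, with a median of 7 H3K27ac regions each. The widest H3K4me1 region lay on chromosome 8 from 124809158 to 124851815 (mm9), spanned 42.7 kb and met 29 H3K27ac regions. The next lay on chromosome 14 from 26286879 to 26326992, spanned 40.1 kb and met 35 H3K27ac regions. Wider regions meet another mark more easily by position alone, which these shares do not correct for.

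The arrangement of H3K4me1 around H3K27ac changed with the strength of acetylation. The share of H3K27ac regions that met an H3K4me1 region rose from 48.5% below 3-fold (13096 regions) to 82.8% from 4-fold to 6-fold (27818 regions) and 96.2% at 20-fold or more (989 regions). The acetylation summit itself lay inside an H3K4me1 region in 42.6% of regions below 3-fold and in 75.1% from 4-fold to 6-fold. It did so in 66.6% from 6-fold to 10-fold, in 28.0% from 10-fold to 20-fold (interval 26.9 to 29.1%) and in 10.4% at 20-fold or more (interval 8.58 to 12.49%). At 1 kb to either side of the summit, H3K4me1 covered 70.2% of positions in the class from 10-fold to 20-fold and 69.2% in the class of 20-fold or more. H3K4me1 was present at 1 kb on both sides but not at the summit in 41.4% of the regions of 20-fold or more (409 of 989, interval 38.3 to 44.5%) and in 1.71% of those below 3-fold. Where H3K4me1 regions of 40 or more summit reads covered 1 kb on both sides, 8.06% of the H3K27ac summits of 10-fold or more lay outside H3K4me1 (51 of 633), against 74.4% of all such summits. This selection by itself lowers the share, because 1 H3K4me1 region that covers both sides contains the summit. The strongest acetylated regions were also wider, with a median of 1987 bp at 20-fold or more against 244 bp below 3-fold.

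**Figure D1:**
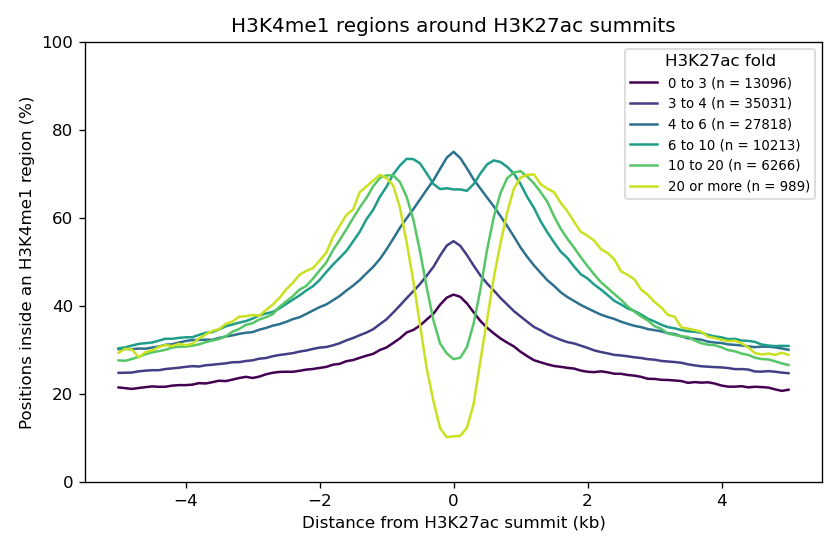
Share of positions (%) inside an H3K4me1 region, in steps of 100 bp from 5 kb before to 5 kb after the H3K27ac summit, for 6 classes of H3K27ac fold (lines; n is the number of regions, 1 library per mark). At the summit the line for 20-fold or more drops to 10.4%, while that for 4-fold to 6-fold peaks at 75.1%.

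The 5 strongest H3K27ac regions that met H3K4me1 all had their summit outside the H3K4me1 region. They lay on chromosome 5 from 115938787 to 115940321 (43.4-fold, 146 summit reads), chromosome 3 from 132345599 to 132347992 (40.8-fold), chromosome 2 from 91549645 to 91552027 and from 164735859 to 164738068 (39.0-fold each), and chromosome 4 from 137149553 to 137151387 (37.8-fold). The 5 strongest regions of H3K27ac alone were all below these in fold. They lay on chromosome 2 from 119302570 to 119304500 (35.5-fold, 119 summit reads), chromosome 7 from 17509477 to 17510021 (28.8-fold), chromosome 1 from 167389785 to 167391183 (28.0-fold), chromosome 2 from 170336624 to 170337381 (26.0-fold) and chromosome 10 from 114687915 to 114688575 (25.4-fold). The second and the fourth of these had a local background 1.39 times the genome-wide one. The strongest regions of H3K4me1 alone lay on chromosome 4 from 59881348 to 59884789 (13.7-fold, 64 summit reads), chromosome 14 from 65962956 to 65965506 (13.5-fold), chromosome 6 from 31359410 to 31368093 (12.6-fold, 8684 bp wide), chromosome 11 from 54027374 to 54029705 (12.6-fold) and chromosome 8 from 122787618 to 122790860 (12.4-fold). No gene is named for these regions because no annotation of the mm9 build was used here.

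The number of acetylated regions per domain ranged widely. Joining neighbouring H3K27ac regions gave 30221 domains, of which 14839 (49.1%) held 1 region and 482 held 20 or more. The 302 domains with the largest acetylated length (the top 1%) held 15.4% of all acetylated length and 11.2% of the regions, with a median span of 89.0 kb and a median of 30 regions. H3K4me1 covered a median of 59.8% of the span of these 302 domains, and 84.3% of their acetylated length lay inside H3K4me1 regions, against 65.9% genome-wide. Of the domains with 1 region, 48.0% met an H3K4me1 region.

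The domain with the largest acetylated length lay on chromosome 6 from 133983590 to 134218398. It spanned 234.8 kb and held 130 H3K27ac regions covering 119.9 kb, and H3K4me1 covered 88.2% of it. The second lay on chromosome 19 from 32212182 to 32464426, with 124 H3K27ac regions over 106.0 kb and H3K4me1 on 79.0% of its span. The third and the eighth were neighbours on chromosome 17, from 84245180 to 84437300 (90.8 kb acetylated) and from 84478949 to 84621078 (64.1 kb acetylated), separated by 41.6 kb. The fourth and the tenth lay on chromosome 11, from 23949442 to 24274013 (86.7 kb acetylated) and from 18764438 to 18937945 (60.8 kb acetylated, 82.4% of the span in H3K4me1). The fifth lay on chromosome 8 from 122847232 to 123088496, where 78.9 kb was acetylated and H3K4me1 covered 89.3%. The sixth, on chromosome 6 from 99109399 to 99484367, was the longest at 375.0 kb and had 68.6 kb acetylated, with H3K4me1 on 43.8%. The seventh lay on chromosome 4 from 154489641 to 154625146 (64.4 kb acetylated, highest summit 24.5-fold) and the ninth on chromosome 14 from 122260317 to 122472556 (63.8 kb acetylated). When gaps of up to 5 kb were joined, 5 of these 10 domains overlapped one of the first 10.

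**Figure D2:**
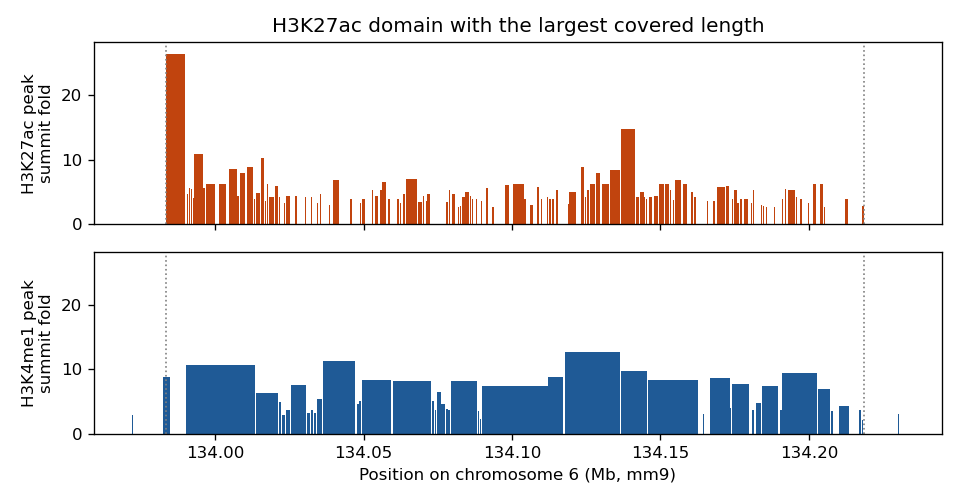
H3K27ac (top) and H3K4me1 (bottom) peaks over the domain with the largest acetylated length, chromosome 6 from 133983590 to 134218398 (dotted lines), with position in Mb (mm9) on the x axis. Each bar spans 1 peak and its height is the authors' fold at the summit, highest at 26.3-fold for H3K27ac.

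Regions of both marks were densest on chromosome 11, least dense among the autosomes on chromosome 14, and sparser still on chromosome X. H3K27ac regions numbered 37.4 per Mb over the 19 autosomes, from 29.99 on chromosome 14 to 54.4 on chromosome 11. H3K4me1 regions numbered 61.5 per Mb, from 49.4 on chromosome 14 to 87.7 on chromosome 11. Chromosome X held 5.72 H3K27ac regions per Mb (954 regions), 6.53 times fewer than the autosomes, and 18.4 H3K4me1 regions per Mb (3067 regions), 3.34 times fewer. On chromosome X 48.4% of H3K27ac regions met H3K4me1, against 67.9 to 77.7% on the autosomes, and 14.4% of H3K4me1 regions met H3K27ac, against 32.3 to 37.3%. H3K4me1 covered 1.20% of chromosome X against 5.47 to 10.8% of the autosomes, and H3K27ac 0.347% against 1.75 to 3.45%. Meetings by position alone are rarer at lower coverage, which these shares do not correct for. Chromosome Y held 4 H3K27ac regions, the strongest from 581508 to 582636 at 20.7-fold with 69 summit reads, and 8 H3K4me1 regions.

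**Figure D3:**
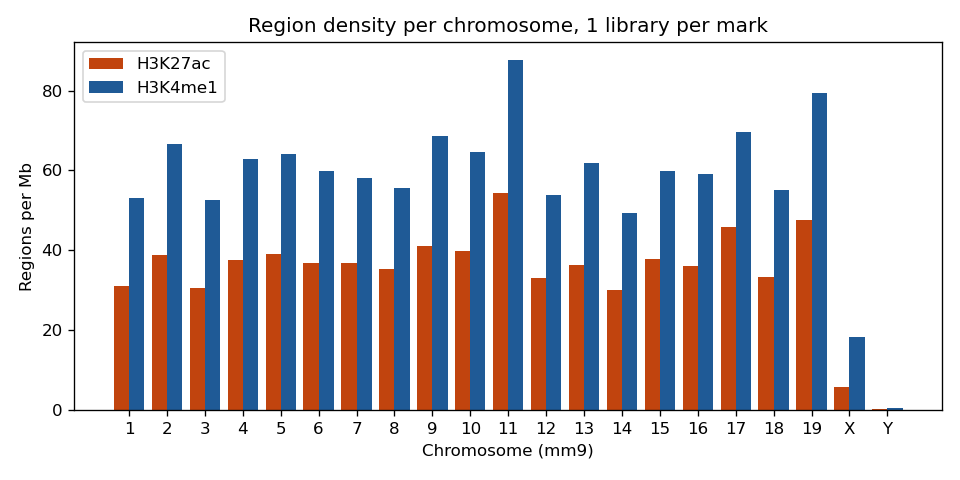
Regions per Mb (y axis) of H3K27ac and H3K4me1 (bars, 1 library per mark) on each mm9 chromosome (x axis). Chromosome 11 is highest for both marks (54.4 and 87.7 per Mb), and chromosome X holds 5.72 and 18.4 per Mb.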

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

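The limit of 5 times used here was chosen after the data had been seen. The local background, a quantity outside the comparison of the marks, reached 5 times the genome-wide level or more at 23 H3K27ac summits and 21 H3K4me1 summits, and 13 of the 23 H3K27ac peaks overlapped such a peak of H3K4me1. The highest lay on chromosome 9 from 3024115 to 3024516 (201 times, 578 H3K27ac reads but 1.21-fold) and on chromosome 2 from 98506885 to 98507314 (118 times, 1.76-fold). On chromosome 11, 8 of the 23 lay between 3031995 and 3103254. The median fold was 2.16 over all 23 H3K27ac peaks and 2.47 over all 21 H3K4me1 peaks, and none of them is named in the results.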

How the results depend on the processing

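The settings limited to the genome-wide background, to the autosomes and to summits inside H3K4me1 were chosen after the results had been seen. Of 38 alternative values, 34 moved, by leaving the counting interval (shares), by a factor over 1.5 (counts) or in the second decimal (ratios of fold). Of the 4 that did not, 2 came from leaving peaks unmerged, which could change nothing because no peaks overlapped. In each setting the share of H3K27ac regions was the larger of the 2 shares, and each ratio of fold stayed above 1. In each pair below the first share is that of H3K27ac regions with H3K4me1 (71.7% as reported) and the second that of H3K4me1 regions with H3K27ac (33.6%). They were 61.9% and 26.6% when 50% of the shorter region had to be shared, 81.6% and 46.1% with a distance of up to 1 kb, 85.3% and 30.8% at a −log10 q of at least 5, and 78.6% and 28.3% at 10. They were 64.9% and 47.6% with equal numbers of regions, 68.3% and 39.5% with regions joined over 1 kb, and 66.8% and 32.2% without the 1% of highest fold. The genome-wide background alone gave 50.2% and 29.2%, where partners were removed from both lists, and the autosomes alone gave 72.0% and 34.0%. For the shares and the ratios of fold, each limit on q was applied to both lists. The ratio of median H3K27ac fold with and without H3K4me1 (1.25 as reported) was 1.17 with 50% shared, 1.18 at a −log10 q of at least 5 and 1.03 at 10. It was 1.09, 1.08 and 1.13 in the narrowest, middle and widest tertiles of width, and 1.12 when the summit had to lie inside H3K4me1. The numbers of H3K27ac and H3K4me1 regions were 38694 and 98566 at a −log10 q of at least 5, and 17960 and 53047 at 10. Joining over 1 kb left 100288 H3K4me1 regions. Domains numbered 45758 with gaps of up to 5 kb and 18750 at a −log10 q of at least 5, against 30221. Of the 10 domains of largest acetylated length, 5 overlapped the first 10 with gaps of up to 5 kb, 6 at a −log10 q of at least 5 and 6 when ranked by fold times width. The cause of the other moves was not tested. The alternatives for gene start sites and gene lists were not run. No paired analysis was possible because each mark has 1 library. Depth limits the H3K4me1-only class, since an H3K27ac summit under 8 reads was never called.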

Other observations

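Of the tests reported here, those of raised background at weak H3K27ac regions and of strong H3K4me1 on both sides of a summit were chosen before their results were seen, and the others after.

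Regions of both marks clustered in the same parts of the autosomes. Across 2463 windows of 1 Mb the numbers of H3K27ac and H3K4me1 regions correlated with a Pearson r of 0.936 and a Spearman rho of 0.964, where windows of 1 library pair are not independent replicates. The densest windows lay on chromosome 11 from 106000001 to 107000000 (171 H3K27ac and 228 H3K4me1 regions) and chromosome 10 from 80000001 to 81000000 (171 and 224). In 219 windows neither mark had a region. On the autosomes and chromosome X, the longest stretches without either mark lay on chromosome X from 23304867 to 33428016 (10.1 Mb) and chromosome 7 from 39057256 to 46703975 (7.65 Mb). Of the 196 such stretches over 1 Mb, 26 were on chromosome X and 170 on the autosomes. On chromosome Y, which these counts leave out, the last region ended at 623459 of 15902555 bp. Assembly gaps and unmappable sequence were not removed from these lengths.

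The low number of regions on chromosome X may come in part from fewer reads there. If each X locus gave fewer reads than an autosomal locus by a factor of 2, X regions with 10, 15, 20 or 25 or more summit reads should be as dense as autosomal regions with 20, 30, 40 or 50 or more, and the ratios were 0.695, 0.847, 0.914 and 0.965 for H3K27ac and 0.550, 0.917, 1.13 and 1.65 for H3K4me1, where the X density lay below the range of the 19 autosomes at the first limit and inside it at the others. An exact halving is argued against only down to 10 reads. X summits of 10 or more reads had a median of 16 reads for both marks (bootstrap intervals 16 to 17 for H3K27ac and 16 to 16 for H3K4me1). Halved reads would give 14 to 15 and 13.5 to 14. At 15 or more and 20 or more reads the X medians lay inside the halved autosomal ranges. They were 22 (range 20.5 to 22) and 27 (25 to 27) for H3K27ac, and 18 (17.5 to 18) and 22 (21.5 to 22) for H3K4me1. Incomplete calling of weak X regions stays open. Fewer marked places at unchanged heights is argued against for H3K4me1, since the autosomal medians were 20 to 21 and the ratio at equal reads dropped from 0.299 at 10 or more to 0.0427 at 25 or more. For H3K27ac the X median of 16 at 10 or more reads lay above the autosomal medians of 13 to 14. At 15 or more it was 22 against 19 to 21, but at 20 or more it was 27 against 28 to 30. The direction thus depended on the limit, and missed weak X regions would also raise the X median. Unchanged heights stay open for H3K27ac. The H3K27ac ratio at equal reads did not drop, at 0.159, 0.221, 0.256 and 0.229 for 10, 15, 20 and 25 or more. Exact halving would give 0.228, 0.261, 0.280 and 0.238, without a drop from the first limit to the last. For H3K27ac the absence of a drop therefore does not tell fewer reads from fewer marked places. A local background above the genome-wide level was also rarer on X, at 7.02% of H3K27ac and 6.39% of H3K4me1 summits against at least 24.1% and 34.9% on any autosome. The labels used here give no sex, although the 4 H3K27ac and 8 H3K4me1 regions on chromosome Y point to at least some DNA from male mice. The number of X copies was not measured, and no biological explanation was tested.

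H3K27ac summits of 10-fold or more mostly lay outside H3K4me1 regions (5400 of 7255, 74.4%), although 93.5% of these regions met H3K4me1. A raised local background that hides H3K4me1 is argued against, since 76.0% (interval 74.9 to 77.1%) lay outside H3K4me1 among the 6205 summits at the genome-wide background. Where H3K4me1 regions of 40 or more summit reads covered 1 kb on both sides, 8.06% (51 of 633, interval 6.06 to 10.5%) lay outside, as a detection limit would give. That test cannot decide, because strong H3K4me1 regions are also wide and 1 region that covers both sides contains the summit. A summit level like that of its flanks, missed for too few H3K4me1 reads, is argued against. It would be called about as often as the flanks. Over the 7255 summits, H3K4me1 covered 70.1% of positions at 1 kb and 25.6% of summits (difference 44.5 percentage points, bootstrap interval 43.3 to 45.8). A lower H3K4me1 level at the summit, under the detection limit, stays open. A candidate explanation is that these summits are active promoters, where H3K4me1 is known to lie beside the start site, and it stays untested because no mm9 annotation was used here.

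H3K27ac regions under 3-fold met H3K4me1 in 48.5% of cases, the lowest of the fold classes. That all of them are noise spread at random over whole chromosomes is argued against. The highest of 100 random placements gave 8.93% and the highest shared shift 9.61%. Neither keeps these regions in the parts of the genome where both marks cluster. Noise that follows those parts was therefore not tested and stays open. A raised local background as the reason for the low share is argued against, since weak regions at the genome-wide background met H3K4me1 in 41.5% of cases (interval 40.4 to 42.6%), more than 10 percentage points below the 86.8% of regions of 4-fold or more. The 5331 weak regions with a raised background met H3K4me1 more often, in 58.8% of cases (interval 57.5 to 60.1%). A mixture of chance peaks and regions whose H3K4me1 is under the detection limit stays open, and no biological explanation was tested.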
